A study of Mus musculus with 6 samples.

How the data were processed

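RNA from 6 cultures of primary mouse aortic smooth muscle cells, 3 WT and 3 KO, was sequenced as stranded, poly(A)-selected paired-end libraries on a NovaSeq instrument per the labels' protocols, which also give a passage of 6 or below. STAR, Partek and DESeq2 and the builds GRCm39 and mm39 are named, without roles or versions, per the submitters' processing notes. Settings of the alignment and counting, and whether strand was used in counting, are not given in the sources used here. The gene coordinates of the deposited comparison table are those of GRCm38: of 12385 genes with an identifier in the GENCODE M21 annotation, 12341 have the same start, so coordinates are given as GRCm38 with the end placed 1 base before the deposited stop.

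A pair of per-library tables was deposited, one under a raw count name and one as normalized counts. Neither holds raw counts. The deposited values are a scaled signal: estimated read counts divided by a factor for each library. In the table used here, 1 read was worth 1.185, 1.167 and 0.791 in WT replicates 1 to 3 and 1.070, 1.156 and 0.712 in KO replicates 1 to 3, found from the low values. Between 82.5% and 92.4% of the values up to 50 reads lay within 0.05 reads of a whole number, which leaves too many fractional values to recover whole reads. The 2 tables share 12365 genes, and 98.0% of their values lie within 0.1% of each other. The genes in the table used here number 12389, and the lowest maximum of any gene was 200.5 estimated reads, a measured property and not a stated filter. The authors' deposited table of the KO against WT comparison gives a p-value and step-up FDR, a log2 ratio and a mean signal per group, and per its file headers the log2 ratio is KO over WT, a sign that its group means bear out.

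Tests for raw counts were chosen before the data were examined. As the deposited values are not counts, limma 3.58.1 (R 4.3.3) with statmod 1.5.0 took their place, on log2(value + 2) with the deposited scaling, for the 12363 genes with a value of at least 10 in at least 3 libraries, and 26 genes were left out. The model had genotype alone, and variances were moderated with a mean trend and robust priors. All p-values are two-sided, and Benjamini-Hochberg adjusted p-values under 0.05 were taken as passing. The group SDs are of the scaled values. The estimated depth of 31.0 to 47.9 M reads per library means that spread between cultures, not counting, sets the precision, with a median residual SD of 0.36 on the log2 scale.

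Same-numbered libraries deviated together from their group means, with correlations across genes of 0.43, 0.15 and 0.39 for replicates 1, 2 and 3. All 3 exceed 0.1, so the numbers were taken to pair the samples, although no label says what a number marks. The main model stayed without the replicate block, as fixed in advance, and the blocked result stands beside each result whose call it changed. With the block the median residual SD was 0.26. The SEs given for genes are those without the block. They can be wider than with it (0.91 against 0.20 for Prc1) or narrower (1.44 against 1.96 for Igfbp2).

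The sample groups, a first set of other settings and 43 gene lists were fixed at the same stage. The lists cover the channel family and NADPH oxidase, inflammation, hypoxia, metabolism, stress, smooth muscle phenotype, other cell types and sex. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with adjustment over the 31 lists that are not markers and over the 3 marker lists apart. Camera with an estimated correlation and fry were run beside it. Symbols were matched by the names of both deposited tables. Genes were named by a fixed rule: the LRRC8 family, up to 12 genes with the largest differences in each direction among those past the threshold with groups that did not overlap and a mean of at least 5 counts per M (symbols of unnamed genes left out), up to 4 members of each list with the smallest p, 2 members of each marker list with the highest level, and the 5 highest genes. Some members that this rule gives are not reported here. As limma called no gene, its largest differences were taken from the genes past an FDR of 0.05 in the authors' deposited table, a choice made after the values were seen.

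The alternatives were recomputed library factors, total scaling, TMM computed by hand, quantile normalization, other filters, pseudocounts of 1 and 10, the other per-library table, limma-voom, variance priors without trend or robust fitting, library quality weights, the replicate block and leaving out each library. Of these, the TMM and quantile scalings, pseudocounts, the other table, the prior settings, the weights and the blocked fits combined with them were added after the data were seen, and the weights after 0 genes had been called. The limma fit without block or weights, and camera, were run on simulated data with each gene drawn independently. Such data hold neither correlation between genes nor the joint deviations of same-numbered libraries. They therefore cannot show the false list calls that correlated genes would cause. With 12363 simulated genes, 200 of them changed between KO and WT at the spread measured here, limma recovered 11.9% of 2-fold, 49.3% of 4-fold and 77.3% of 8-fold changes with 6 false calls. With 10 percent biological spread it recovered 100% at each of these sizes with 7 false calls. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, using pandas 2.3.3 and numpy 2.4.6.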

Results

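Messenger RNA was sequenced from primary aortic vascular smooth muscle cells, the contractile cells of the arterial wall, grown from pieces of mouse thoracic aorta and collected without any treatment at passage 6 or below. Of the 6 libraries, 3 came from wild-type (WT) mice and 3 from mice whose smooth muscle lacked LRRC8A (KO), a leucine-rich repeat protein that is the essential subunit of the volume-regulated anion channel. The submitters described them as independent biological replicates, and their stated interest lay in inflammation, hypoxia signalling, metabolism and cellular stress. The genotype field reads wild type for all 6 samples, so the groups were taken from the sample titles. The estimated read totals were 33.1, 31.0 and 45.4 M in WT replicates 1 to 3 and 35.9, 31.6 and 47.9 M in KO replicates 1 to 3. Values are scaled read counts as deposited, and fold changes are log2(value + 2) differences, KO over WT, from limma, which understate the change of low genes.

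Lrrc8a, the targeted gene (ENSMUSG00000007476, GRCm38 chromosome 2, 30237715 to 30263790), had 2578, 2194 and 1221 scaled reads in WT replicates 1 to 3 and 868, 672 and 506 in KO replicates 1 to 3. The group values were 1997 ± 700 in WT and 682 ± 181 in KO (SD, n = 3 each). All 3 KO libraries lay below all 3 WT libraries, which is the direction the titles give. The other 4 family members, which join LRRC8A in the channel, went in different directions. Lrrc8e had 44.6 ± 17.6 scaled reads in WT and 180 ± 22.5 in KO (SD, n = 3 each), with all 3 KO libraries above all 3 WT libraries. Lrrc8b, Lrrc8c and Lrrc8d had log2 fold changes of 0.04 (SE 0.41), -0.13 (SE 0.39) and -0.17 (SE 0.58), and the sign of each turned when 1 of the libraries was left out.

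The limma log2 fold change of Lrrc8a was -1.51 (SE 0.34) and that of Lrrc8e 2.03 (SE 0.59), each with an adjusted p of 0.999 over all genes, so neither passed. With library quality weights, a setting chosen after the values were seen, Lrrc8a passed at an adjusted p of 0.045. With the weights and the replicate block it did not pass (0.0562), and over all settings but the weights alone its adjusted p ran from 0.0562 to 1. Of the 5 family members, 2 passed when adjusted over the list alone and 0 over all genes tested by limma, where 2 had an unadjusted p under 0.05. An exact two-sided permutation test gave p = 0.1 for each of the pair, the smallest that 3 libraries against 3 allow. In the authors' deposited table Lrrc8a had a log2 ratio of -1.55 at a false discovery rate (FDR) of 0.0196, and in the authors' deposited table Lrrc8e had 2.01 at 0.0369. The predicted gene Gm28035 (chromosome 2, 30240567 to 30282148) overlaps Lrrc8a, and its values of 383, 354 and 184 in WT and 123, 96.9 and 8.27 in KO are uncertain because the counting may have divided shared reads. Gm28035 was added after its values were seen.

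**Figure D1:**
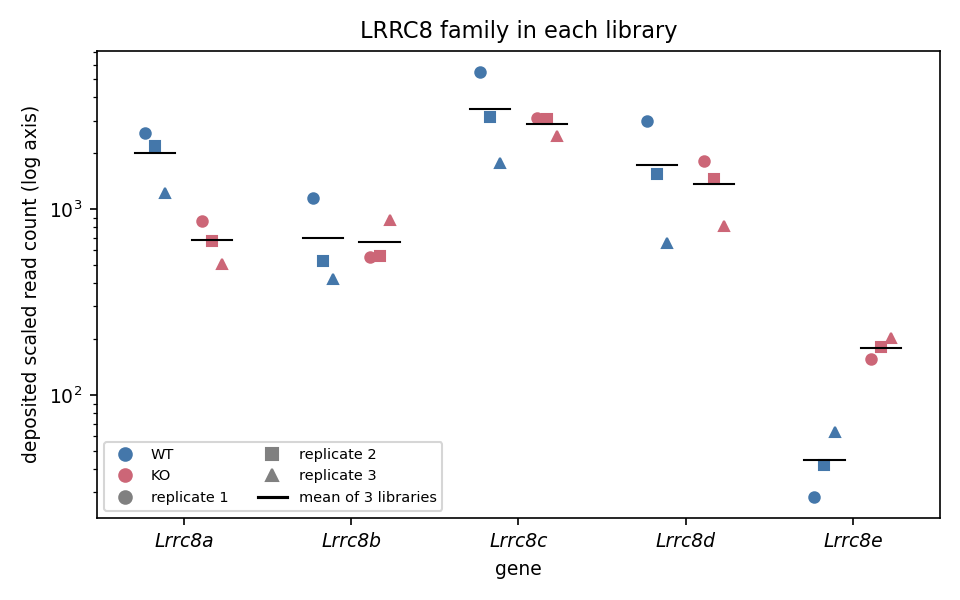
Deposited scaled read counts (log axis) of the 5 LRRC8 genes in each of the 6 libraries, with WT in blue, KO in red, a marker shape per replicate number and a line at the mean of 3 libraries. Lrrc8a lies at 506 to 868 in KO against 1221 to 2578 in WT, and Lrrc8e at 157 to 202 in KO against 28.4 to 63.3 in WT.

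Among the genes with the largest differences, Fmod, which encodes the collagen-binding proteoglycan fibromodulin, had 9416 ± 3811 scaled reads in WT and 1485 ± 222 in KO (SD, n = 3 each). Icam1, a leukocyte adhesion molecule, had 8285 ± 2952 in WT and 1623 ± 186 in KO, and Gas6, a ligand of the TAM receptor tyrosine kinases, had 15023 ± 1999 and 2567 ± 1346 (SD, n = 3 each). In the other direction, Fat4, an atypical cadherin, had 1676 ± 240 in WT and 3937 ± 366 in KO, and Igfbp6, an insulin-like growth factor binding protein, had 2206 ± 1088 and 8950 ± 3326 (SD, n = 3 each). These 5 genes were named under a rule that admits only genes whose KO and WT libraries do not overlap. In the authors' deposited table all 5 were past an FDR of 0.05.

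No gene passed an adjusted p of 0.05 in limma, with 0 higher and 0 lower in KO among the 12363 genes tested. The smallest adjusted p was 0.274, and 447 genes had an unadjusted p under 0.05, of which 181 were higher and 266 lower in KO. limma-voom gave 0 genes with 429 at an unadjusted p under 0.05, limma with the replicate block gave 0 with 917, and limma-voom with the block gave 0 with 1099. limma with library quality weights, chosen after these counts were seen, gave 6 higher and 24 lower with 2284 at an unadjusted p under 0.05. The same weights with the replicate block gave 1 higher and 4 lower with 1735. Without KO replicate 1, limma called 1 gene, Glipr1, lower at an adjusted p of 0.0268. KO and WT libraries did not overlap for 1042 genes, or 8.4% of those tested, where chance gives 10% if the libraries are exchangeable. Same-numbered libraries deviated together, so that 10% does not hold strictly here. No value that allows for this was computed, so the share cannot be judged against chance.

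The authors' deposited table holds 65 genes at an FDR under 0.05, with 14 higher and 51 lower in KO. Of the 65 genes in the authors' deposited table, 60 were tested here, all 60 had the same sign in limma, and 59 had an unadjusted p under 0.05. Both fits rest on the same libraries, so this accord is no independent support. Of the 65 genes, 3 had a value of 10 or more in at most 1 library. Since limma called no gene, the rule for naming the largest changes was applied to the FDR of the authors' deposited table, a choice made after the values were seen. It gave 10 genes higher in KO. By limma log2 fold change these were Fibin (2.73, SE 0.77), Spon2 (2.54, SE 0.60), Aldh1a7 (2.35, SE 0.52), Igfbp6 (2.12, SE 0.48), Angpt2 (1.94, SE 0.47), Obsl1 (1.49, SE 0.30), Pknox2 (1.45, SE 0.30), Plcl1 (1.39, SE 0.30), Fat4 (1.24, SE 0.19) and Grb14 (1.04, SE 0.20). Angpt2 is a ligand of the endothelial receptor Tie2, and Grb14 an adaptor that binds the insulin receptor. The 12 named genes lower in KO had limma log2 fold changes from -5.70 for Angptl7 to -2.30 for Icam1. Between them lay Mfap4, a microfibril-associated protein (-4.44, SE 1.12), Gdf6, a growth factor of the bone morphogenetic protein family (-4.22, SE 0.85), Eef1a2 (-3.98, SE 1.09), Glipr1 (-3.47, SE 0.53), the nuclear receptor Nr4a3 (-3.07, SE 0.70), Fads6 (-2.73, SE 0.52), Gas6 (-2.67, SE 0.38), Fmod (-2.60, SE 0.30), Crct1 (-2.56, SE 0.84) and Cyb561 (-2.44, SE 0.59).

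**Figure D2:**
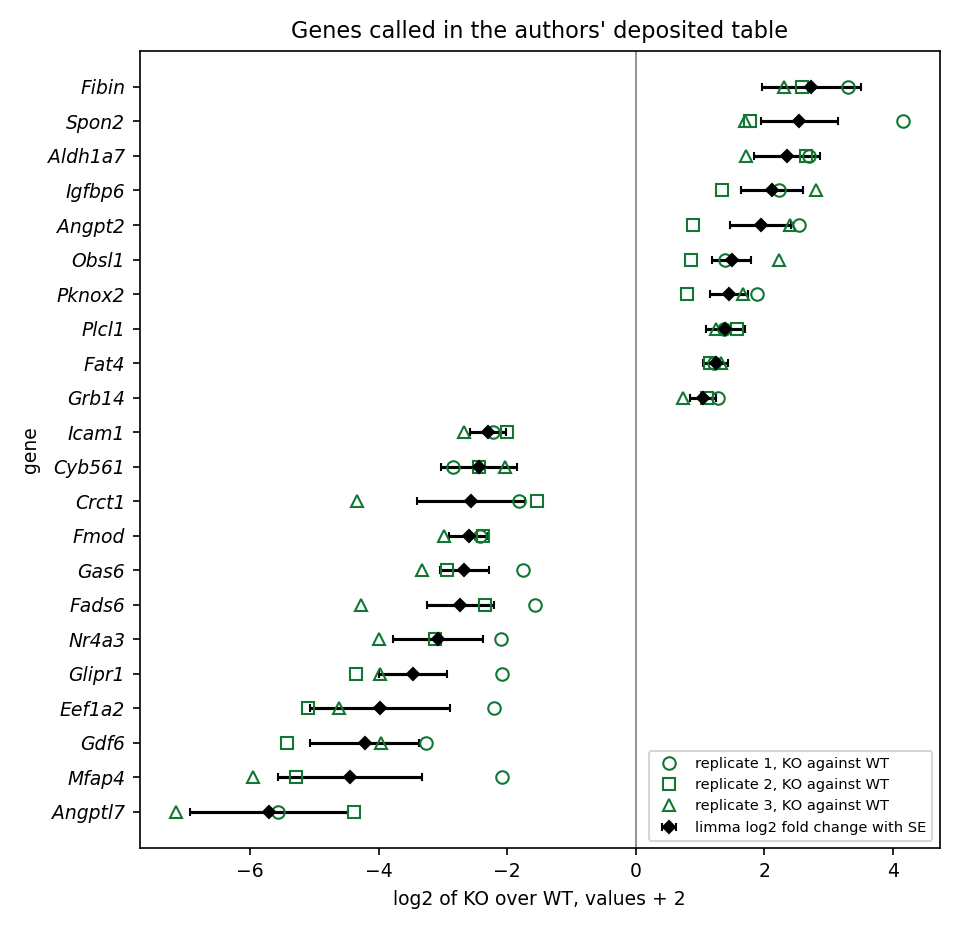
Log2 of KO over WT, on values + 2, for the 22 genes named from the authors' deposited table, with the limma estimate and its SE as a black diamond and each same-numbered pair of libraries as an open green marker. The estimates run from -5.70 for Angptl7 to 2.73 for Fibin, and since only genes whose groups did not overlap could be named, the shared sign of the pairs follows from the selection.

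In the list of 34 tested nuclear factor kappa B (NF-kB) and cytokine genes the median log2 fold change was -0.58, and 27 of 34 members had a value below 0. Icam1 (log2 fold change -2.30, SE 0.28), the prostaglandin synthase gene Ptgs2 (-1.66, SE 0.33), the macrophage growth factor Csf1 (-1.20, SE 0.32) and the chemokine Ccl7 (-2.27, SE 0.75) each had all 3 KO libraries below all 3 WT libraries. These members were named for the smallest p in the list, so the lack of overlap follows largely from that choice. Among all tested genes 8.4% did not overlap. Ccl7 was parted narrowly, at 1483 in KO replicate 3 against 1588 in WT replicate 1. Interferon-stimulated genes, 28 tested, had a median of -0.28, with Lgals3bp at -1.43 (SE 0.53), Ifi35 at -0.36 (SE 0.20), Parp14 at -1.52 (SE 0.86) and Eif2ak2 at -0.21 (SE 0.19). The median of the interferon list by pair was -1.03, 0.35 and -0.30 in replicates 1, 2 and 3, and that of the NF-kB list -0.81, -0.38 and -0.26.

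The NF-kB list passed camera at an adjusted p of 5.89e-06, and its adjusted p = 0.556 with an estimated correlation did not pass, where the unadjusted p was 0.0206. The interferon list passed camera at an adjusted p of 0.0399, with adjusted p = 0.872 with an estimated correlation. In the NF-kB list 2 members passed adjusted over the list alone, 5 did with the replicate block, and 0 passed over all genes in limma, where 8 had an unadjusted p under 0.05. In the interferon list 0 passed adjusted over the list alone and 0 over all genes in limma, with 1 at an unadjusted p under 0.05. The 4 tested leukocyte markers had a median log2 fold change of -0.79 and the 6 tested epithelial and mesothelial markers one of -1.49, in the same direction as both lists. The NF-kB list passed without each library in turn, at adjusted p from 1.55e-06 to 0.00164. The interferon call was lost without WT replicate 1 (adjusted p = 0.603), WT replicate 2 (0.174), KO replicate 1 (0.406) or KO replicate 3 (0.949), and with library quality weights (0.708).

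HIF target genes, those induced by hypoxia-inducible factors, had a median log2 fold change of -0.24 over 33 tested members, 22 of them below 0. The glucose transporter Slc2a1 had 3241 ± 530 scaled reads in WT and 1410 ± 327 in KO (SD, n = 3 each), a log2 fold change of -1.21 (SE 0.24), and the prolyl hydroxylase Egln3 had -1.46 (SE 0.51). Ppp1r3c, a glycogen-targeting subunit, and Vldlr, a lipoprotein receptor, went the other way at 1.90 (SE 0.57) and 1.35 (SE 0.56). HIF pathway regulators had a median of 0.11 over 9 tested members, with Hif1a at -0.47 (SE 0.31), Egln2 at 0.22 (SE 0.25), Siah2 at 0.23 (SE 0.27) and Cited2 at -0.19 (SE 0.27).

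The HIF target list passed camera at an adjusted p of 0.0349, with adjusted p = 0.556 with an estimated correlation, and with the replicate block the camera adjusted p was 0.055 and the call was lost. In that list 1 member, Slc2a1, passed adjusted over the list alone, 4 passed with the block, and 0 passed over all genes in limma, where 4 had an unadjusted p under 0.05. The HIF target call was also lost without WT replicate 1 (adjusted p = 0.491), KO replicate 2 (0.0849) or KO replicate 3 (0.118), and with library quality weights (0.246). The regulator list did not pass (camera adjusted p = 0.742), with 0 members adjusted over the list alone and 0 at an unadjusted p under 0.05 in limma.

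Of 21 glycolysis genes 18 had a log2 fold change below 0, with a median of -0.35 and with Slc2a1 at -1.21 (SE 0.24), the hexokinase Hk2 at -1.09 (SE 0.40), the phosphofructokinase Pfkp at -1.12 (SE 0.47) and the lactate dehydrogenase Ldhb at -1.71 (SE 0.61). Of 26 genes of cholesterol synthesis and uptake 24 were above 0, with a median of 0.60, and 15 were above 0 in all 3 same-numbered pairs. The sterol synthesis genes Mvd, Dhcr7 and Fdps had 1.25 (SE 0.35), 0.94 (SE 0.37) and 0.89 (SE 0.40), and Ggps1, which makes geranylgeranyl diphosphate, had -0.65 (SE 0.31). Fatty acid synthesis genes, 14 tested, had a median of 0.30, with the desaturases Fads2, Scd2 and Scd1 at 0.86 (SE 0.32), 0.96 (SE 0.58) and 0.80 (SE 0.57) and the acetyl-CoA synthetase Acss2 at 1.02 (SE 0.48).

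Camera passed glycolysis at an adjusted p of 7.30e-05, with adjusted p = 0.556 with an estimated correlation. It passed cholesterol genes at an adjusted p of 7.25e-06, with adjusted p = 0.872 with an estimated correlation, and fatty acid synthesis at 0.031, with adjusted p = 0.872 with an estimated correlation. In glycolysis 1 member, Slc2a1, passed adjusted over the list alone, 0 did with the replicate block, and 0 passed over all genes in limma, with 4 at an unadjusted p under 0.05. In the cholesterol list 0 passed adjusted over the list alone, 9 passed with the replicate block, 1 of them lower in KO, and 0 passed over all genes in limma, with 2 at an unadjusted p under 0.05. In fatty acid synthesis 0 passed adjusted over the list alone and 0 over all genes, with 1 at an unadjusted p under 0.05 in limma. The cholesterol call was lost without WT replicate 3 (adjusted p = 0.112) or KO replicate 1 (0.0751), the fatty acid synthesis call without WT replicate 2 (0.127), WT replicate 3 (0.345) or KO replicate 1 (0.796), and the glycolysis call with library quality weights (0.0578).

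Mitochondrial lists lay near 0. Nuclear-encoded oxidative phosphorylation genes had a median log2 fold change of 0.00 over 49 members (camera adjusted p = 0.846), with Ndufs8 at 0.51 (SE 0.21), Sdhc at -0.42 (SE 0.33) and Sdha at -0.21 (SE 0.18). The 13 transcripts of the mitochondrial genome had a median of -0.03 (camera adjusted p = 0.846), with mt-Cytb at -0.27 (SE 0.63), mt-Nd3 at -0.10 (SE 0.51), mt-Nd4 at -0.13 (SE 0.71) and mt-Atp6 at -0.09 (SE 0.52). They made up 7.13%, 4.95% and 1.82% of the values in WT replicates 1 to 3 and 6.41%, 4.24% and 2.37% in KO replicates 1 to 3. Tricarboxylic acid cycle genes had a median of -0.04 over 22 members (camera adjusted p = 0.845), with Pcx at -0.41 (SE 0.24), Dlat at -0.35 (SE 0.22), Dlst at 0.29 (SE 0.18) and Cs at 0.41 (SE 0.28). Fatty acid oxidation had 0.08 over 21 members (camera adjusted p = 0.599), with Cpt1a at 0.31 (SE 0.20), Echs1 at 0.41 (SE 0.27) and Acaa2 at 0.29 (SE 0.21). One-carbon and serine synthesis had a median of 0.02 and a mean of -0.11 over 12 members (camera adjusted p = 0.845, tested as higher), with Gldc at -2.04 (SE 1.39), Psat1 at 0.41 (SE 0.28), Mthfd1 at 0.27 (SE 0.25) and Tyms at 0.54 (SE 0.60). In these 5 lists 0 members passed adjusted over the list alone and 0 over all genes in limma, with 1, Ndufs8, at an unadjusted p under 0.05. Without WT replicate 3 the oxidative phosphorylation list passed as higher and the mitochondrial genome list as lower (adjusted p = 0.00322 each), and without KO replicate 3 the first passed as lower (0.0404). Without KO replicate 1 the one-carbon list passed as higher (adjusted p = 0.00652).

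The NRF2, endoplasmic reticulum stress, ATF4 and immediate-early lists passed camera as lower in KO at the preset correlation. None of the 4 passed when it was estimated, at adjusted p = 0.556, 0.813, 0.872 and 0.705 with an estimated correlation. NRF2 antioxidant genes had a median log2 fold change of -0.37, with 27 of 33 below 0, among them the glutathione transferases Mgst1 (-1.18, SE 0.28) and Gsta3 (-1.61, SE 0.59), the glutathione synthesis gene Gclm (-0.81, SE 0.19) and the carbonyl reductase Cbr1 (-0.47, SE 0.19). Endoplasmic reticulum stress genes had a median of -0.21, with 21 of 24 below 0, among them the sensors Atf6 (-0.83, SE 0.27) and Eif2ak3 (-0.73, SE 0.25) and the folding proteins Pdia4 (-0.54, SE 0.20) and Sdf2l1 (-0.40, SE 0.26). ATF4 response genes had a median of -0.18 over 31 members, with the transcription factor Atf3 at -2.23 (SE 0.51), Nupr1 at -1.08 (SE 0.26) and Chac1 at -1.22 (SE 0.40), and Vldlr at 1.35 (SE 0.56). Immediate-early genes had a median of -0.18 over 22 members, with Ier3 at -0.89 (SE 0.27), Junb at -0.57 (SE 0.18) and Nr4a1 at -1.19 (SE 0.40).

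Camera passed NRF2 genes at an adjusted p of 5.89e-06, with adjusted p = 0.556 with an estimated correlation. It passed endoplasmic reticulum stress at 0.00249, with adjusted p = 0.813 with an estimated correlation. ATF4 genes passed at 0.0251, with adjusted p = 0.872 with an estimated correlation, and immediate-early genes at 0.0205, with adjusted p = 0.705 with an estimated correlation. In these 4 lists 0 members passed adjusted over the list alone and 0 over all genes in limma, with 5, 3, 4 and 4 at an unadjusted p under 0.05. With the replicate block 5 ATF4 genes and 2 immediate-early genes passed adjusted over the list alone. The NRF2 list passed without each library in turn, at adjusted p from 9.92e-07 to 6.47e-04. The endoplasmic reticulum stress call was lost without WT replicate 1 (adjusted p = 0.229) or KO replicate 3 (0.0969), and the immediate-early call without WT replicate 1 (0.215), WT replicate 2 (0.174) or KO replicate 3 (0.145). The ATF4 call was lost without WT replicate 2 (adjusted p = 0.158), WT replicate 3 (0.218), KO replicate 1 (0.701) or KO replicate 3 (0.0679), and with library quality weights (0.0728).

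Heat shock genes (median 0.00, camera adjusted p = 0.674), p53 targets (median -0.02, mean -0.08, tested as higher, camera adjusted p = 0.846) and tonicity-responsive genes (median -0.17, mean 0.03, tested as lower, camera adjusted p = 0.599) did not pass. Leading members were the small heat shock genes Hspb1 (-1.06, SE 0.42) and Cryab (-0.53, SE 0.29), with Hsf2 (-0.23, SE 0.28) and Hsph1 (0.22, SE 0.37). The p53 list was led by Tigar (-0.69, SE 0.25), Gdf15 (-1.62, SE 0.70), Sesn1 (0.55, SE 0.28) and Bbc3 (0.67, SE 0.35), and the tonicity list by the transporters Slc6a6 (-0.70, SE 0.34) and Aqp1 (1.41, SE 1.08) with Akr1b3 (-0.81, SE 0.39) and Cldn1 (1.46, SE 1.07). In these 3 lists 0 members passed adjusted over the list alone and 0 over all genes in limma, with 2, Hspb1 and Tigar, at an unadjusted p under 0.05. Without WT replicate 1 the p53 list passed as lower (adjusted p = 0.0366), and with library quality weights the heat shock list did (0.0103). With the block 1 heat shock gene and 1 p53 target passed adjusted over the list alone.

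**Figure D3:**
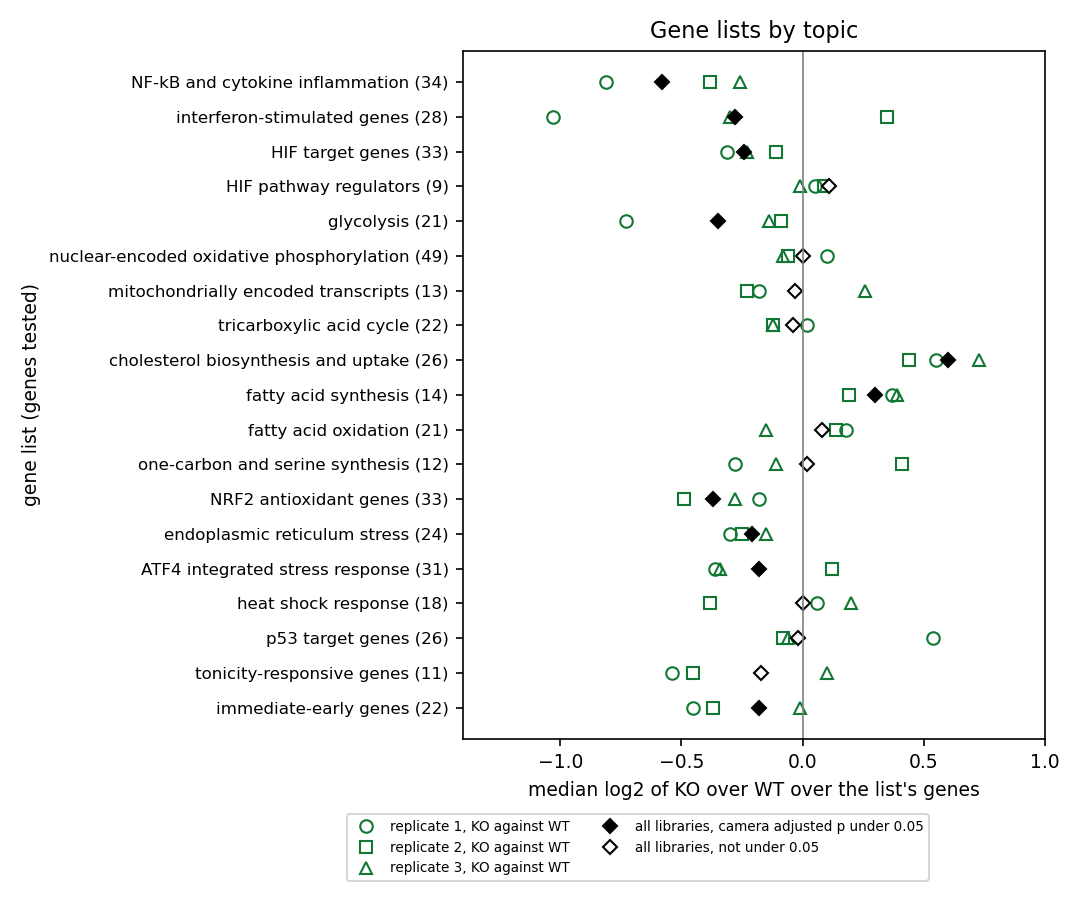
Median log2 of KO over WT over the tested genes of each list on inflammation, hypoxia, metabolism and stress, with a diamond for all libraries (filled where the camera adjusted p with a preset correlation was under 0.05) and open green markers for the 3 same-numbered pairs. The medians run from -0.58 for the NF-kB list to 0.60 for the cholesterol list, and no list passed with an estimated correlation.

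Contractile smooth muscle genes had a median log2 fold change of -0.28 over 25 tested members, 16 of them below 0. The integrin Itga7 had -2.01 (SE 0.61), the smooth muscle myosin gene Myh11 -2.63 (SE 1.16) and Lmod1 -2.46 (SE 1.37). The contractile genes Acta2 and Tagln, chosen after their values were seen, had 0.14 (SE 1.02) and 0.56 (SE 1.23). Proliferation genes had a median of 0.48 over 40 members, 38 of them above 0, with pair medians of -0.10, 0.78 and 0.77 in replicates 1, 2 and 3. Among them were Ccne2 at 0.60 (SE 0.39), Rrm2 at 0.90 (SE 0.78), Prc1 at 0.98 (SE 0.91) and Cdc6 at 0.81 (SE 0.76). Lysosome and autophagy genes had a median of -0.23, with 25 of 33 below 0, among them the lysosomal hydrolases Glb1 (-0.79, SE 0.20) and Gla (-0.86, SE 0.27), the proton pump subunit Atp6v1h (-0.50, SE 0.21) and Atg7 (-0.40, SE 0.20).

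Camera passed the contractile list at an adjusted p of 0.0173, with adjusted p = 0.872 with an estimated correlation. Proliferation passed at 0.00189, with adjusted p = 0.872 with an estimated correlation, and lysosome genes at 5.94e-04, with adjusted p = 0.705 with an estimated correlation. In these 3 lists 0 members passed adjusted over the list alone and 0 over all genes in limma, with 1, 0 and 2 at an unadjusted p under 0.05. The contractile list turned to higher without WT replicate 3 (adjusted p = 0.91), and its call was lost without KO replicate 2 (0.297) and with library quality weights (0.208). The proliferation list turned to lower without KO replicate 3 (adjusted p = 0.471) and its call was lost without WT replicate 1 (0.688). The lysosome call was lost without KO replicate 3 (adjusted p = 0.152). Over the 31 lists tested outside the cell type markers, 13 passed camera, 10 lower and 3 higher in KO. Of these, 0 passed camera with an estimated correlation, where 2 had an unadjusted p under 0.05, and 0 passed fry.

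In limma with all 6 libraries and no block, the 7 other lists on cell phenotype did not pass camera. Fibrillar and network matrix genes had a median of 0.24 (camera adjusted p = 0.108), and passed with the replicate block at 0.0247, with adjusted p = 0.426 with an estimated correlation. Mfap4 (-4.44, SE 1.12), the matrix glycoprotein gene Thbs1 (0.72, SE 0.28), Fbln1 (-3.33, SE 1.31) and the collagen Col5a1 (0.80, SE 0.35) led that list. Modulated smooth muscle and osteochondrogenic genes had a median of -0.19 (camera adjusted p = 0.347), with Fmod (-2.60, SE 0.30) the 1 member past the threshold adjusted over the list alone and with Alpl at -2.55 (SE 1.42), Sox9 at 0.61 (SE 0.38) and Ly6a at 0.69 (SE 0.54). Matrix proteases and inhibitors had -0.12 (camera adjusted p = 0.339), with Plau at -0.81 (SE 0.27), Adam19 at -0.79 (SE 0.33), Adamts4 at -1.27 (SE 0.56) and Mmp11 at 0.47 (SE 0.24). TGF-beta response genes had 0.15 (camera adjusted p = 0.846), with Junb at -0.57 (SE 0.18), Id3 at 0.60 (SE 0.46) and Skil at 0.29 (SE 0.24). YAP-TEAD targets had -0.22 (camera adjusted p = 0.269), with Igfbp3 at -4.37 (SE 0.99), the coagulation initiator F3 at -1.32 (SE 0.34), Arhgef17 at 0.40 (SE 0.21) and Nuak2 at -0.74 (SE 0.53). RhoA and actin genes had 0.05 (camera adjusted p = 0.599), with Vasp at 0.45 (SE 0.22), Rhob at 0.70 (SE 0.41), Cfl2 at 0.35 (SE 0.24) and Vcl at -0.66 (SE 0.47). PI3K-AKT and FOXO genes had a median of 0.20 and a mean of -0.01 (camera adjusted p = 0.599, tested as higher), with Igfbp2 at -4.23 (SE 1.44), Irs1 at 0.63 (SE 0.23), Gadd45a at -1.04 (SE 0.42) and Klf15 at -0.63 (SE 0.32).

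In these 7 lists 1 member, Fmod, passed adjusted over the list alone and 0 over all genes in limma. Those at an unadjusted p under 0.05 numbered 3 in the fibrillar matrix list, 1 in the modulated list, 2 among proteases, 1 among TGF-beta genes, 2 among YAP-TEAD targets, 0 among RhoA genes and 3 among PI3K-AKT genes. With the block 1 member each of the fibrillar, modulated, protease, YAP-TEAD and PI3K-AKT lists passed adjusted over the list alone. The fibrillar matrix list also passed with limma-voom (adjusted p = 0.0382) and without KO replicate 2 (0.0181) or KO replicate 3 (0.046). Without KO replicate 2 the modulated list (adjusted p = 0.0165) and the proteases (0.0261) passed as lower, as the YAP-TEAD targets did without WT replicate 2 (0.0303).

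Ion channels and transporters had a median of -0.14 (camera adjusted p = 0.22), with the sodium-calcium exchanger Slc8a1 at -1.99 (SE 0.71) and Slc12a7 at -1.42 (SE 0.93). In that list 0 members passed adjusted over the list alone and 0 over all genes in limma, with 1 at an unadjusted p under 0.05, and 1 passed adjusted over the list alone with the block. The list passed as lower without WT replicate 3 (adjusted p = 4.75e-04) or KO replicate 2 (0.0365). The LRRC8 family as a list had a median of -0.13 and a mean of 0.05 (camera adjusted p = 0.846, tested as lower). Of the NADPH oxidase subunits 4 were tested, Rac1 (0.24, SE 0.20), Cyba (0.22, SE 0.40), Poldip2 (-0.12, SE 0.22) and Nox4 (0.10, SE 0.28), too few for a list test, and Nox1 is not analysed here.

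Genes listed here as markers of other cells of the aorta were expressed in both groups. These libraries do not show which cells made the transcripts, so the levels do not establish that other cell types were present. The fibroblast markers Gsn and Serpinf1 had 21810 ± 715 and 14300 ± 10150 scaled reads in WT and 27675 ± 6906 and 12543 ± 10220 in KO (SD, n = 3 each), and the mural marker Pdgfrb 25721 ± 3406 and 25650 ± 7043. The mesothelial markers Upk3b and Msln had 4336 ± 1812 and 1831 ± 1492 in WT and 1835 ± 1312 and 1111 ± 1332 in KO (SD, n = 3 each). Of the 3 marker lists with 5 or more tested members, fibroblast (median -0.11), epithelial and mesothelial (-1.49) and pericyte (-0.53), none passed camera, at adjusted p of 0.714, 0.448 and 0.448. In these 3 lists limma had 0 members past the threshold over all genes, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05, and with the block 1 epithelial and mesothelial marker passed adjusted over the list alone. Without KO replicate 2 the epithelial and mesothelial list passed as lower (adjusted p = 0.0286). Shorter marker lists gave values alone, with Cd14 at -0.89 (SE 0.46) and Csf1r at -0.70 (SE 0.50) for leukocytes. Outside the naming rule, Lyz2 had -1.32 (SE 0.49), at an unadjusted limma p of 0.0302, and Cd68 had -0.52 (SE 0.81). Endothelial markers had Eng at 2.36 (SE 1.62) and Flt1 at -1.34 (SE 1.20), with a list median of -0.14. Adipocyte markers had Lpl at 2.46 (SE 2.25) and Plin4 at -0.20 (SE 1.47), median 0.10, and neural markers Mbp at 0.30 (SE 0.39) and Tubb3 at 0.21 (SE 0.75), median 0.21. The striated muscle gene Tnnt2 had 1.17 (SE 1.07) and the mural gene Notch3 -0.20 (SE 0.66). No lymphocyte marker was tested.

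The first principal component, 41% of the variance, ordered the libraries of each genotype by replicate number, with scores of -53.4, -16 and 51.4 in WT replicates 1 to 3 and -38.6, -15.4 and 72 in KO replicates 1 to 3. Pearson correlations of log2 values ran from 0.814 to 0.928 between pairs of libraries, across genes within these libraries. Acta2, the smooth muscle actin gene, had 10651, 13083 and 130984 scaled reads in WT replicates 1 to 3 and 18724, 21829 and 59317 in KO replicates 1 to 3, and the proliferation marker Mki67 had 736, 1887 and 5332 in WT and 707, 4423 and 9529 in KO. These 2 genes were chosen after their values were seen. KO replicate 2 had 21672 scaled reads of Xist, the X-inactivation transcript, against at most 7.11 in the other libraries. It had 1.16 of the Y-linked Ddx3y and 0 of Eif2s3y, against at least 1339 and 335. The genotypes were thus not balanced in sex-linked transcripts, and no fit included sex. The most abundant transcripts were mt-Co1, Fn1, Eef1a1, Fbln2 and mt-Cytb, with log2 fold changes of -0.05 (SE 0.69), 0.39 (SE 0.43), 0.08 (SE 0.31), -0.36 (SE 0.40) and -0.27 (SE 0.63).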

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

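The tests of Xist, of Lrrc8a in KO replicate 2 and of the library quality weights were chosen after the result was seen, and the NF-kB list was picked for weighing because it had the smallest camera p.

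The low-value filter left out 26 genes, and 13 of these reached at least 100 in 1 KO library and more than 10 times their highest WT value, a limit chosen for this search. They were Rnf17 (204), Hoxc10 (517), Ifi202b (364), Hc (184) and Grk3 (263) in KO replicate 3, Nxph2 (228) and Xlr3b (1921) in KO replicate 1, and Car6 (347), Cntnap5b (551), C2cd6 (279), Xist (21672), Otogl (312) and Gm5253 (617) in KO replicate 2. Eya2, Tspan11, Gm15725 and Gm16867 were also higher in a KO library than in any WT library, by less than that limit. The search covered KO libraries alone. The same limit turned to WT was met by Ptgds (275) in WT replicate 1 and by Glp1r (295) and Ptger3 (340) in WT replicate 2. It was also met by Gbgt1 (212), Prdm16 (534), Gm10134 (352) and Lhx8 (370) in WT replicate 3.

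KO replicate 2 held Xist at 21672 and the Y-linked Uty and Eif2s3y at 0. The X-linked genes that escape inactivation, Kdm6a, Eif2s3x, Ddx3x and Kdm5c, had a median log2 ratio of 0.85 in this library against the mean of the other 5, so a female donor may account for the pattern. Loss of the Y chromosome in culture is argued against by Xist at 21672, and an exchange of the KO and WT labels by Lrrc8a at 672, against 1221 in the lowest WT library. The sex of the donors is not given in the labels, and no biological explanation beyond it was tested. If this donor was female, sex was unbalanced between the genotypes in each KO against WT estimate and list test, and no fit included sex. Without KO replicate 2 the camera adjusted p of the interferon list went from 0.0399 to 3.68e-08. That change cannot be assigned to sex, since leaving out 1 library removes all its other traits as well.

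The NF-kB list was lower in KO by camera, with a median log2 fold change of -0.58, and did not pass at adjusted p = 0.556 with an estimated correlation. With the mesothelial marker score as a covariate the median was -0.35 at a camera adjusted p of 1.23e-04, so part of the shift stayed beside that score. Without each library in turn the largest camera adjusted p was 0.00164, so the call did not need any 1 library. Both used the preset correlation. At that setting other splits of the libraries gave this list unadjusted camera p of 2.03e-04, 0.00261, 0.0157 and 0.0261. These p-values therefore exclude neither mesothelial content nor a single library. The mean list score was -0.12 in both WT replicate 3 and KO replicate 2. With the leukocyte marker score as a covariate the median was -0.13 at a camera adjusted p of 0.237. That score itself separated the groups, at 0.74, 0.58 and -0.04 in WT replicates 1 to 3 and -0.98, -0.08 and -0.23 in KO. Because the score follows genotype, this fit cannot tell leukocyte content from genotype, and leukocyte content stays open. With this score the fold was smaller and the spread wider, and which of these ended the camera call was not tested. The SD over members went from 1.19 to 1.48 and the median SE from 0.56 to 0.83. The residual degrees of freedom went from 4 to 3, and only 4 of 15 leukocyte markers were measured. The genotype named by the design stays open beside leukocyte content, untested apart from the comparison itself.

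Genes near Lrrc8a were tested for DNA of another strain linked to the targeted allele. Of the 216 genes within 10 Mb, 2.8% had an unadjusted p under 0.05 in limma. The 95th percentile was 6.5% for runs of the same size along the genome. With the replicate block the share was 4.2% against 11.1%. The window as a whole thus held no excess of differences. The share cannot exclude a few linked genes or a cluster nearer to Lrrc8a. Without the block, Cercam, Tbc1d13, Gm28035 (which overlaps Lrrc8a), Prrx2 and Lcn2, between 29869164 and 32388252, had an unadjusted p under 0.05. Stom, further off at 35313986, had one as well. Whether linked DNA of another strain underlies these was not tested.

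The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. limma called 0 genes at an adjusted p under 0.05 in the real split and at most 0 in the others, so 10 of 10 gave as many, and limma-voom also called 0 in the real split. With library quality weights the real split gave 30 genes and the highest other 0, so 1 of 10 gave as many. The weights were taken up after the real split had given 0 genes, so the splits were not treated alike in this comparison. At an unadjusted p under 0.05 the real split gave 447 genes and the highest other 1616, and 5 of 10 gave as many. That other split sets WT replicates 1 and 2 with KO replicate 1 against the rest, and so many genes point to a structure of the samples along the replicate numbers. For lists past camera the real split gave 13 and the highest other 16, and 5 of 10 gave as many, the 4 others being splits that keep 2 same-numbered pairs together. The camera p of the NF-kB list was 2.88e-07 in the real split and 2.03e-04 in the nearest other, so 1 of 10 gave one as small. This list was picked for its small p in the real split, so the comparison favours that split. The smallest p of any list in each split was not compared. Among the 4 splits that part all 3 same-numbered pairs, the genes at an unadjusted p under 0.05 numbered 447 in the real split and 291, 144 and 207 in the others, and with the replicate block 917 against 697, 301 and 448. Lists past camera numbered 13 in the real split and 4, 11 and 6 in these others.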

How the results depend on the processing

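The settings added after the data were seen are the pseudocounts, TMM and quantile scaling, the other per-library table, the trend and robust settings, the library quality weights, and the combinations of the replicate block with these, with limma-voom or with an estimated correlation. The fits for raw counts chosen earlier, edgeR and DESeq2, were not run, because the deposited values are not counts, and the settings named within them were run in limma. limma called 0 genes higher and 0 lower, with 447 at an unadjusted p under 0.05, and limma-voom also 0, so the stricter thresholds, an adjusted p under 0.01 or a fold change of at least 1.5, could give no other count and test nothing. Lrrc8a was lower in KO under each setting run, with log2 fold changes from -1.29 without WT replicate 1 to -1.83 without WT replicate 3. No scaling moved the median of all genes by more than 0.031. Where a value below differs from the report, the cause was not tested. At 31.0 to 47.9 M estimated reads per library, depth limits only the low genes.

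Values in brackets here are camera adjusted p for lists and log2 fold changes for genes. With the replicate block the camera call was lost for HIF target genes (0.055) and gained for fibrillar and network matrix (0.0247), both also without robust or trend settings, and the block changed no other list or gene call over all genes. limma-voom, with or without robust spread, gained fibrillar and network matrix (0.0382). The block with limma-voom, with or without robust spread, lost the calls of interferon-stimulated genes (0.418) and HIF target genes (0.0547) and gained fibrillar and network matrix (0.0195). In it the lists nuclear-encoded oxidative phosphorylation (0.959) and p53 target genes (0.936) and the genes Tubb3 (-0.01) and Ddx3y (0.54) reversed. Quantile normalization reversed mt-Co1 (0.1). Library quality weights gave 6 genes higher and 24 lower in KO, against 0 and 0, and a log2 fold change of -1.62 for Lrrc8a, which passed. They lost the calls of interferon-stimulated genes (0.708), HIF target genes (0.246), glycolysis (0.0578), ATF4 integrated stress response (0.0728) and contractile smooth muscle (0.208), and gained heat shock response (0.0103). The lists nuclear-encoded oxidative phosphorylation (0.767), p53 target genes (0.287), modulated smooth muscle and osteochondrogenic (0.869), TGF-beta response (0.115) and YAP-TEAD targets (0.614) reversed, as did the genes Cyba (-0.03), Nox4 (-0.06), Hsph1 (-0.19), Id3 (-0.09), Vcl (0.15), Lpl (-0.39) and Fbln2 (0.15). The weights with the block gave 1 higher and 4 lower. They lost interferon-stimulated genes (0.871), HIF target genes (0.111) and ATF4 integrated stress response (0.357). The lists nuclear-encoded oxidative phosphorylation (0.748), p53 target genes (0.678), modulated smooth muscle and osteochondrogenic (0.964) and TGF-beta response (0.397) and the genes Lrrc8b (-0.04), Nox4 (-0.01) and Fbln2 (0) reversed.

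With an estimated correlation the 13 lists lost their camera call, at adjusted p of 0.556 for NF-kB and cytokine inflammation, 0.872 for interferon-stimulated genes, 0.556 for HIF target genes, 0.556 for glycolysis and 0.872 for cholesterol biosynthesis and uptake. For fatty acid synthesis, NRF2 antioxidant genes, endoplasmic reticulum stress, ATF4 integrated stress response and immediate-early genes they were 0.872, 0.556, 0.813, 0.872 and 0.705. For contractile smooth muscle, proliferation and lysosome and autophagy they were 0.872, 0.872 and 0.705. With the block and an estimated correlation the adjusted p were 0.426 for NF-kB and cytokine inflammation, 0.829 for interferon-stimulated genes, 0.426 for HIF target genes, 0.581 for glycolysis and 0.426 for cholesterol biosynthesis and uptake. For fatty acid synthesis, NRF2 antioxidant genes, endoplasmic reticulum stress, ATF4 integrated stress response and immediate-early genes they were 0.444, 0.426, 0.426, 0.426 and 0.426. For contractile smooth muscle, proliferation and lysosome and autophagy they were 0.581, 0.581 and 0.426. With fry they were 0.543 for NF-kB and cytokine inflammation, 0.969 for interferon-stimulated genes, 0.576 for HIF target genes, 0.576 for glycolysis and 0.969 for cholesterol biosynthesis and uptake. For fatty acid synthesis, NRF2 antioxidant genes, endoplasmic reticulum stress, ATF4 integrated stress response and immediate-early genes they were 0.969, 0.576, 0.76, 0.969 and 0.969. For contractile smooth muscle, proliferation and lysosome and autophagy they were 0.969, 0.969 and 0.76. fry also reversed LRRC8 family (0.983).

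Leaving out each library in turn gave 0 to 1 genes lower in KO, the 1 being Glipr1 without KO replicate 1. The lists and genes below each changed call or direction without at least 1 library. For LRRC8 family, interferon-stimulated genes and HIF target genes the adjusted p ran from 0.144 to 0.913, 3.68e-08 to 0.949 and 0.0184 to 0.491. For nuclear-encoded oxidative phosphorylation, mitochondrially encoded transcripts and one-carbon and serine synthesis the adjusted p ran from 0.00322 to 0.834, 0.00322 to 0.848 and 0.00652 to 0.941. For endoplasmic reticulum stress, p53 target genes and tonicity-responsive genes the adjusted p ran from 1.63e-04 to 0.229, 0.0366 to 0.945 and 0.0639 to 0.971. For immediate-early genes, YAP-TEAD targets and proliferation the adjusted p ran from 1.38e-04 to 0.215, 0.0303 to 0.913 and 4.06e-19 to 0.688. For ion channels and transporters of smooth muscle, fatty acid synthesis and fatty acid oxidation the adjusted p ran from 4.75e-04 to 0.983, 4.73e-04 to 0.796 and 0.0883 to 0.989. For ATF4 integrated stress response, heat shock response and matrix proteases and inhibitors the adjusted p ran from 2.17e-04 to 0.701, 0.068 to 0.933 and 0.0261 to 0.989. For RhoA and actin regulation, adventitial fibroblast and tricarboxylic acid cycle the adjusted p ran from 0.112 to 0.837, 0.104 to 0.839 and 0.118 to 0.931. For cholesterol biosynthesis and uptake, contractile smooth muscle and TGF-beta response the adjusted p ran from 6.72e-14 to 0.112, 3.03e-04 to 0.91 and 0.224 to 0.964. For modulated smooth muscle and osteochondrogenic, fibrillar and network matrix and PI3K-AKT and FOXO responses the adjusted p ran from 0.0165 to 0.609, 0.0181 to 0.632 and 0.174 to 0.905. For epithelial and mesothelial and lysosome and autophagy the adjusted p ran from 0.0286 to 0.826 and 1.63e-04 to 0.152.

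For Lrrc8c, Lrrc8d, Cyba and Nox4 the log2 fold change ran from -0.54 to 0.27, -0.73 to 0.35, -0.24 to 0.56 and -0.06 to 0.24 when a library was left out. For mt-Cytb, mt-Nd3, mt-Nd4 and mt-Atp6 the log2 fold change ran from -0.83 to 0.21, -0.53 to 0.29, -0.8 to 0.4 and -0.52 to 0.32 when a library was left out. For Plin4, Tubb3, mt-Co1 and Eef1a1 the log2 fold change ran from -1.64 to 1.02, -0.26 to 1.1, -0.67 to 0.43 and -0.06 to 0.25 when a library was left out. For Lrrc8b, Serpinf1, Pdgfrb and Poldip2 the log2 fold change ran from -0.26 to 0.47, -1.03 to 0.56, -0.19 to 0.21 and -0.26 to 0.02 when a library was left out. For Lpl, Notch3, Fbln2 and Ddx3y the log2 fold change ran from -0.28 to 4.06, -0.74 to 0.41, -0.6 to 0.02 and -5.16 to 0.55 when a library was left out. For Tyms, Hsph1 and Msln the log2 fold change ran from -0.01 to 1.07, -0.08 to 0.58 and -2.89 to 0.51 when a library was left out.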

Other observations

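All genes in this part were chosen after their values were seen.

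Several genes past the FDR threshold in the authors' deposited table lie outside the gene lists. Gfpt2, an enzyme of the hexosamine pathway, had 3367 ± 391 scaled reads in WT and 820 ± 211 in KO (SD, n = 3 each), a limma log2 fold change of -2.06 (SE 0.24). Gch1, the first enzyme of tetrahydrobiopterin synthesis, had 886 ± 207 and 197 ± 42.6, and Sod3, the extracellular superoxide dismutase, 18024 ± 9481 and 3498 ± 967 (SD, n = 3 each). The cytokine receptor genes Osmr and Lifr had log2 fold changes of -0.67 (SE 0.17) and -1.22 (SE 0.25). Pdpn, a membrane glycoprotein, had -1.62 (SE 0.37), Plpp3, a lipid phosphate phosphatase, -1.22 (SE 0.28), and Stom, a membrane scaffold protein, -0.88 (SE 0.19). Stom lies within 10 Mb of Lrrc8a. The smallest limma adjusted p among these genes was 0.274, so none passed.

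With library quality weights limma called 30 genes, of which 26 were past the FDR threshold in the authors' deposited table. They include Gfpt2 (adjusted p = 0.0141), Gas6 (0.0228), Gch1 (0.0228), Ptgs2 (0.0339), Lrrc8a (0.045), Slc2a1 (0.045) and Nupr1 (0.045). The weights gave WT replicate 2 a weight of 7.99 and the other libraries 0.36 to 1.97, so that fit rests largely on 1 WT library. With the weights and the replicate block 5 genes passed, namely Igfbp3, Fmod, Gfpt2, Icam1 and Fibin. Of the genes given with a p-value above, only Gfpt2 kept its call.

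Tagln, a contractile gene, had 2240, 8008 and 58393 scaled reads in WT replicates 1 to 3 and 10030, 8327 and 40463 in KO replicates 1 to 3. Top2a, a cell division gene, had 1112, 2036 and 5230 in WT and 1032, 4472 and 9233 in KO. Of the 21 Hox genes tested, 0 had an unadjusted p under 0.05 in limma, and their median log2 fold change was 0.16. That summary hides wide differences between libraries of the same genotype in some Hoxc genes. Hoxc6 had 4.74, 1349 and 1361 in WT replicates 1 to 3 and 106, 1698 and 1639 in KO replicates 1 to 3. Hoxc8 had 0, 685 and 66.5 in WT and 53.5, 292 and 2249 in KO. Hoxc9 had 0, 46.7 and 0.791 in WT and 4.28, 10.4 and 1030 in KO. Hoxb6 was more even, at 1534, 1517 and 1478 in WT and 1771, 1240 and 1383 in KO.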
